A study of Mus musculus with 7 samples.

How the data were processed

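The samples were 7 cultures of macrophages grown from mouse bone marrow, 1 Affymetrix array each, and every label carries the replicate number 2. Arrays with other replicate numbers are not analysed here. Per the labels, cultures were kept for 24 h with medium, MDP or Pam3CSK4 and then for 3 h with medium, MDP or Pam3CSK4. No culture had a pretreatment without a second ligand.

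The deposited values are expression per probe set on the log2 scale, made with RMA from the affy package per the submitters' processing notes. Neither the versions, the probe set definitions nor the set of arrays normalized together is stated. The values ran from 2.95 to 15.1 over 45101 probe sets, and no values were missing or transformed again. Array medians were 5.50 (naive unstimulated), 5.55 (naive with MDP), 5.54 (naive with Pam3CSK4), 5.48 (MDP before MDP), 5.53 (Pam3CSK4 before MDP), 5.54 (Pam3CSK4 before Pam3CSK4) and 5.50 (MDP before Pam3CSK4). Of scale, centring and direction, none was left unknown for these values, since the scale is stated, no centring per gene is seen and higher values mean more signal.

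Gene symbols came from the platform table. Of the probe sets 64 were controls, 34945 had 1 symbol, 932 several and 9160 none, and 34741 of those with 1 symbol had their gene identifier in the RefSeq gene table, with 0 symbols updated from it. Each of 18193 genes was represented by the probe set with the highest mean over the 7 arrays among those with exactly 1 symbol, and 9010 genes had more than 1 such probe set.

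Differences were taken between pairs of single arrays in 13 comparisons, and no p-value is given. The number of arrays limits the precision, and no spread between cultures can be estimated. Genes at least 3-fold over unstimulated in naive cells were called induced, and 2-fold was the threshold for differences between pretreated and naive cells and between ligands. A fold is 2 to the power of the log2 difference. Where 1 of the 2 values lay below the median of its array, the difference was counted from that median and is given as a bound, and where both did none is given, a rule chosen after the results were seen. Counts, list medians and figures use the deposited values. The unstimulated value was below that median for 2 of the 40 MDP-induced genes and 33 of the 232 Pam3CSK4-induced genes, and 40 and 220 stayed past 3-fold at the bound. Percentages of induced genes carry exact 95% binomial intervals over genes, which describe the gene set and not the spread between cultures. These thresholds, the gene lists, the comparisons and the alternative settings, except the counting of single probe sets, were fixed before the data were examined.

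There were 23 gene lists with 407 members, of which 366 had a probe set with their single symbol. The other members are not analysed here. The lists were cytokines, chemokines, interferon-stimulated genes, NF-kB feedback genes, immediate early genes, antimicrobial and tissue effector genes, pattern recognition and scavenger receptors, Toll-like receptor and NOD signalling components, costimulation and antigen presentation, survival and apoptosis, sterol synthesis, glycolysis and hypoxia, oxidative stress, cell cycle, alternative activation, macrophage identity, housekeeping genes, and markers of neutrophils, T and NK cells, B cells, dendritic cells, stromal cells, and mast cells and erythroid cells. Each list median was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Overlaps of sets that share the unstimulated array were set beside the overlap of independent lists and beside 100 simulated sets of unchanged arrays with a common control. The simulated spread was that of the closest pair of arrays, Pam3CSK4 before MDP and Pam3CSK4 before Pam3CSK4, shuffled over genes. Pairs of comparisons that share no array were also compared.

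The genes named are the 10 highest and 5 lowest past the threshold in each naive comparison, the 10 lowest and 5 highest induced genes in each pretreatment comparison, the 5 highest in each direction between ligands, up to 4 members per list and comparison, and a fixed set of genes of macrophage activation. Any other gene is said to have been chosen after its values were seen.

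The calculation was tested on simulated data with 18193 genes in 1 array against 1. The spread was again that of the closest pair of arrays, so the test does not cover variation between cultures. Of 50 genes raised 2-fold, 0 were past 3-fold, all 50 were past it at each of 4-fold, 8-fold and 16-fold, and 0 genes without a raise were. Alternatives were centring the arrays on their medians or on housekeeping genes, cyclic loess (span 0.7, 3 iterations), the mean of a gene's probe sets, leaving out less specific probe sets, requiring the higher array to lie above its median or 75th percentile, adding 32 to the linear values, other fold thresholds, and genes chosen by the other ligand. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for cyclic loess.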

Results

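Gene expression was measured on Affymetrix arrays in mouse macrophages grown from bone marrow. The cells were kept for 24 h without ligand (naive) or with 1 of 2 bacterial products (pretreated), and then for 3 h without ligand or with either product. MDP is muramyl dipeptide, a fragment of the peptidoglycan of bacterial cell walls that is sensed inside the cell. Pam3CSK4 is a synthetic triacylated lipopeptide that is sensed at the cell surface by the Tlr2 and Tlr1 proteins. The 7 groups were naive unstimulated, naive with MDP, naive with Pam3CSK4, MDP before MDP, Pam3CSK4 before MDP, Pam3CSK4 before Pam3CSK4 and MDP before Pam3CSK4, with 1 array each. Every difference below is therefore between 2 arrays and has no replicate check, and the number of arrays limits the precision. The questions were which genes each ligand induced in naive cells, at a threshold of 3-fold over unstimulated cells, and which of those stood more than 2-fold lower in pretreated cells given a ligand. Differences are on the log2 scale unless a fold is given, and 18193 genes were compared. A value below the median of its array cannot be told from background, so a difference against such a value is counted from that median and written as a bound. Some of these bounds were smaller with 32 added to the linear values or with the mean of a gene's probe sets.

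In naive macrophages given MDP, 40 genes were at least 3-fold higher than in unstimulated macrophages, and 106 at least 2-fold. Among the 40, 15 genes had several probe sets above the array median, and in 5 of these all probe sets were past 3-fold. Acod1, the enzyme that makes itaconate, stood highest at 32.1-fold over unstimulated. It was followed by the neutrophil chemoattractant Cxcl3 at 12.8-fold, the oxidized lipoprotein receptor Olr1 at 10.9-fold, the fatty acid receptor Gpr84 at 9.63-fold and the C-type lectin Clec4e at 8.58-fold. Il1b, which encodes interleukin-1 beta, was 8.36-fold higher, the membrane-bound protease Mmp14 8.01-fold, the chemokine Cxcl10 7.60-fold, the early activation marker Cd69 6.76-fold and Socs3, a feedback inhibitor of cytokine signalling, 7.07-fold. The transporter gene Slc16a12 was the only gene 3-fold lower by the deposited values, with a difference of -1.19 or lower, and with 32 added to the linear values 0 genes were. With the mean of a gene's probe sets Mmp14 was at 2.06, and without less specific probe sets Socs3 was at 2.15.

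Of the 21 measured chemokine genes, 6 were 3-fold higher with MDP, among them Cxcl2 (2.42) and Ccl5 (2.18). Cxcl11 was another of the 6, but was at 0.94 with the mean of its probe sets. Cxcl1 was not, but was past 3-fold (1.75) without less specific probe sets. Among the cytokine genes, Il1a (at least 1.88) and Il1b were the only members of 21 past the threshold, while Tnf was at 0.91 and Il10 at 0.11, and Il6 and Il12b were below the array median on both arrays. All 27 measured interferon-stimulated genes lay above the unstimulated level, with a median of 0.95, and 1 of them, Ifit1, was past 3-fold (1.81). Among 27 feedback and negative regulators of NF-kB signalling, Socs3, Nfkbie (2.27) and Relb (1.74) were past the threshold, and Nfkbia (0.43), Tnfaip3 (0.67) and Irak3 (0.47) were not. Tlr2 itself was 4.30-fold higher, with Olr1 and Clec4e the other pattern recognition and scavenger receptors past 3-fold among 20. Cd40 (2.71), Cd69, Icam1 (1.85) and Cd83 (1.61, just short of it with the arrays centred on their medians) were the 4 of 21 costimulation and antigen presentation genes past it. The medians of the chemokine, interferon-stimulated, NF-kB and cytokine lists were each at percentile 100 of 10000 random lists of the same size matched on mean expression, as a description of these arrays.

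More genes were past 3-fold with Pam3CSK4 in naive cells, which holds only for the single dose used of each ligand. Il1b was 180.5-fold higher than in unstimulated cells, Il1a at least 92.9-fold, the acute phase gene Saa3 129.7-fold, Socs3 112-fold, Il6 at least 20.2-fold and Ptgs2, the inducible cyclooxygenase, at least 38.9-fold. Acod1 was 61.0-fold higher, Cxcl3 53.1-fold, Mmp14 40.2-fold and the costimulatory receptor Cd40 38.2-fold. In total 232 genes were at least 3-fold higher (413 at 2-fold), 220 of them also at the bound, and 110 at least 3-fold lower, or 73 with the mean of a gene's probe sets. Among the 232, 112 genes had several probe sets above the array median, and in 63 of these all probe sets were past 3-fold. Among the lowest were the RNA-binding protein gene Mex3b (-2.55 or lower), the cannabinoid receptor Cnr2 (-3.36), the MAP kinase phosphatase Dusp6 (-3.28), thrombomodulin, Thbd (-3.20), and the unnamed transcript C130050O18Rik (-3.17, or -2.55 with 32 added to the linear values). With the mean of a gene's probe sets Mmp14 was at 4.15 and Cd40 at 5.90.

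With Pam3CSK4, 10 of 21 cytokine genes were past 3-fold, including Tnf (3.57) and Il10 (3.07). Il12b was among them by the deposited values only, and was higher by at least 0.87. Of the chemokine genes 11 of 21 were past 3-fold, including Cxcl2 (5.08), Ccl5 (4.87) and Cxcl1 (4.31, or 6.66 without less specific probe sets). The list medians were 1.58 and 1.82. Of the NF-kB feedback genes 14 of 27 were 3-fold higher, including Nfkbiz (4.15, or 3.55 with the mean of its probe sets) and Dusp2 (3.29). Inpp5d, an inositol phosphatase gene, was at -1.59, or -1.32 with the mean of its probe sets, and was chosen after its values were seen. Among antimicrobial and tissue effector genes 11 of 22 were 3-fold higher, with the prostaglandin synthase Ptges (at least 3.76) and Lcn2, which binds bacterial siderophores (2.23), while Nos2 was at 0.90 and Camp at 0.56. The interferon-stimulated list had a median of 0.83, with Gbp3 (2.00) and Gbp2 (1.90) past the threshold and Irf7 (0.08) close to its unstimulated level. Of the Toll-like receptor and NOD signalling components 5 of 20 were past 3-fold, among them Traf1 (at least 5.07, or 4.11 with the mean of its probe sets). Survival and apoptosis genes went both ways, with 6 of 15 3-fold higher, led by Gadd45b (3.11), and Gadd45a 3-fold lower (-2.16). Mertk, a receptor for apoptotic cells, was also 3-fold lower (-2.29), and Tlr4, the lipopolysaccharide receptor, was at -1.76, or -1.14 with the mean of its probe sets. The medians of the cytokine, chemokine, NF-kB and antimicrobial lists were at percentile 100 of the matched random lists.

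**Figure D1:**
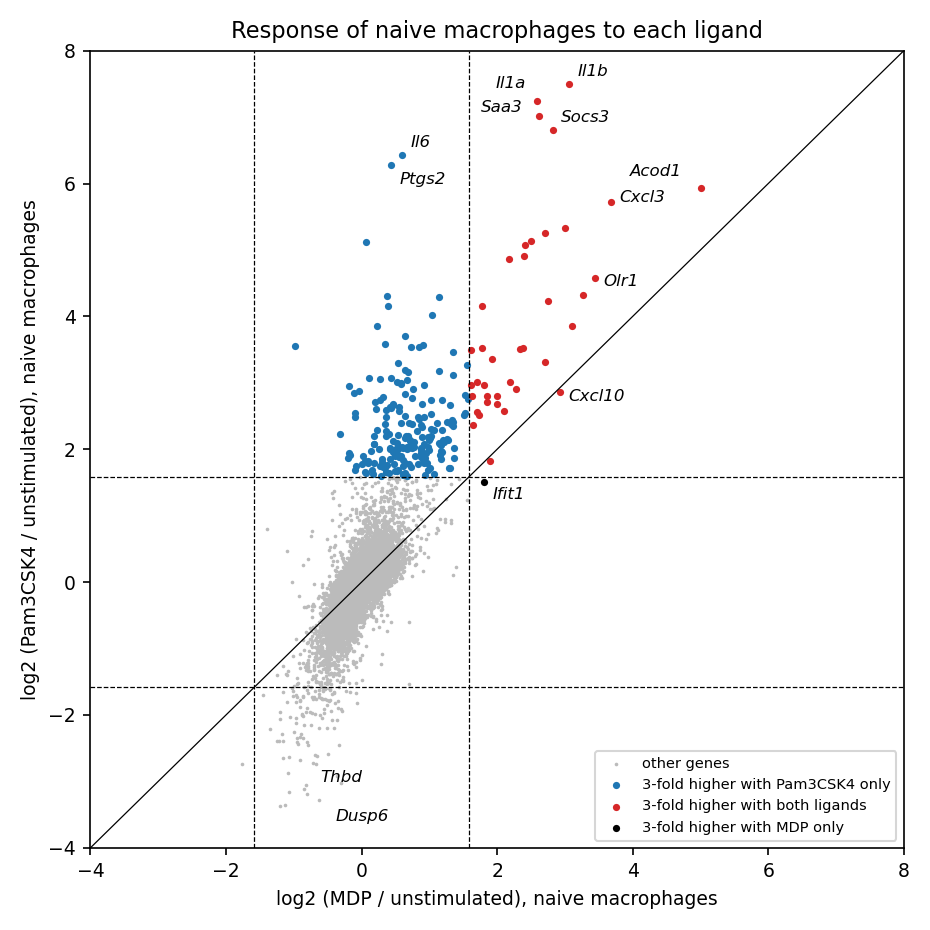
Each point is a gene, placed by its log2 ratio over unstimulated cells with MDP (x axis) and with Pam3CSK4 (y axis) in naive macrophages, 1 array per condition. Dashed lines mark 3-fold, the solid line marks equal ratios, and colours mark the 39 genes past 3-fold with both ligands, the 193 with Pam3CSK4 alone and Ifit1 with MDP alone.

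Nearly every MDP-induced gene was also induced by Pam3CSK4, and to a higher level at these doses. The induced sets shared 39 genes, 37 of which were higher with Pam3CSK4 and 24 of which were at least 2-fold higher. Il1b was 21.6-fold higher with Pam3CSK4 than with MDP, Cxcl2 6.32-fold and Acod1 1.90-fold, whereas Cxcl10 differed by 0.07. Ifit1, an interferon-induced protein with an antiviral role, was the gene past 3-fold with MDP alone, and with Pam3CSK4 it lay close below the threshold at 1.51. With the arrays centred on housekeeping genes Ifit1 was past 3-fold with both. Over the MDP-induced genes the median fold was 4.69 with MDP and 11.4 with Pam3CSK4. Over the Pam3CSK4-induced genes it was 4.87 with Pam3CSK4 and 1.67 with MDP, and 219 of the 232 lay above the unstimulated level with MDP. All 110 genes that were 3-fold lower with Pam3CSK4 lay below that level with MDP. Set directly against each other, the naive arrays had 255 genes at least 2-fold higher with Pam3CSK4 (105 at 3-fold), including Ptgs2 (at least 37.7-fold), Il6 (at least 19.6-fold), Shisa3 (at least 12.1-fold), Il1a (25.3-fold) and the integrin Itgb8 (at least 5.51-fold). There were 129 at least 2-fold higher with MDP, or 80 with the mean of a gene's probe sets and 28 at 3-fold, including the G protein regulator Rgs2 (6.61-fold, or a log2 difference of 2.07 with the mean of its probe sets), Dusp6 (6.31-fold), the chemokine receptor Cxcr4 (5.90-fold), Thbd (5.27-fold) and Hmga2-ps1 (at least 4.55-fold). Against unstimulated, Rgs2 was at -0.30 with MDP and -3.02 with Pam3CSK4, or -2.30 with the mean of its probe sets, and Cxcr4 at -0.36 and -2.93. Both induced sets rest on the same unstimulated array. Independent lists of these sizes would share 0.510 genes, and simulated unchanged arrays against a common control shared 0. The simulated spread came from the closest pair of arrays (robust SD 0.111), shuffled over genes. The simulation is therefore set to a small spread and does not bound variation between cultures. Over genes the differences from unstimulated had a Pearson r of 0.764 and a covariance of 0.101, against 0.499 and 0.00939 in the simulation. Genes are not independent replicates, and part of the excess may come from the shared control array.

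After MDP pretreatment, a second exposure to MDP gave lower levels of MDP-induced genes than a first exposure, by an amount that depends on how the genes are chosen. Olr1 was 6.75-fold lower than in naive cells given MDP, Gpr84 5.39-fold, Socs3 4.71-fold, the small GTPase effector Cdc42ep2 4.12-fold, Clec4e 3.72-fold, Cd40 3.54-fold and Acod1 3.06-fold. The zinc finger genes Hivep3 and Mllt6 were 3.46-fold and 3.39-fold lower, and the NF-kB inhibitor gene Nfkbie 3.06-fold. With the mean of a gene's probe sets Hivep3 (-0.46) and Mllt6 (-0.92) were short of 2-fold. They were then also short of 3-fold with MDP in naive cells, as were some others of the 40. Of the 40 MDP-induced genes, 31 (77.5%) were more than 2-fold lower, with an exact 95% binomial interval over genes from 61.5% to 89.2%, and the median difference was -1.32. With induction at 2-fold 42.5% were 2-fold lower, with lowering at 3-fold 10 of the 40, and of the genes induced by Pam3CSK4 19.8%. The chemokine gene Ccl5 alone was more than 2-fold higher (1.25), and Saa3 (0.58), Calhm6 (-0.71), Ifit1 (-0.73) and Il1b (-0.90) were the next highest. In MDP-pretreated cells 7 of the 40 genes (17.5%) were still at least 3-fold over unstimulated, and 37.5% at least 2-fold. The median over unstimulated was 0.90, against 2.23 in naive cells given MDP. Il1b was at 2.16 and Acod1 at 3.39 over unstimulated, Tlr2 at 0.81 and Socs3 at 0.58.

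By gene group, 5 of 27 NF-kB feedback genes were 2-fold lower after MDP pretreatment, including Relb (-1.31) and Nfkb2 (-1.23, or -0.88 with the mean of its probe sets), with a list median of -0.35. Of the chemokine genes 4 of 21 were 2-fold lower, including Cxcl3 (-1.34) and Cxcl10 (-1.32), with a median of -0.35, with Ccl5 on the other side. The cytokine median was -0.21, with Il1a past 2-fold (-1.46) and Tnf (-0.80) and Il1b short of it. Of 27 interferon-stimulated genes 20 were above the naive level. Irf7 (1.67), Oas3 (1.49), Isg20 (1.43) and Zbp1 (1.21) were 2-fold higher after pretreatment, Irf1 was near the 2-fold line on the lower side (-1.04), and the list median was 0.34. Over all genes 70 were at least 2-fold higher and 53 at least 2-fold lower than in naive cells given MDP. With the mean of a gene's probe sets in place of the brightest, these counts were 44 and 34. With 32 added to the linear values they were 37 and 42, and at 3-fold 8 and 11, which turns the order of the counts. Of the 7 measured B cell marker genes Ighm, the immunoglobulin mu chain, was the 1 past 2-fold, 4.01-fold lower in the pretreated cells, though the mean of its probe sets differed by -0.51.

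After Pam3CSK4 pretreatment, a second exposure to Pam3CSK4 left some induced genes close to or below the unstimulated level and others above their level in naive cells. Shisa3 was at least 12.2-fold lower than in naive cells given Pam3CSK4, the dendritic cell maturation marker Cd83 18.6-fold, the transcription factor Egr2 at least 12.7-fold, Snn at least 12.2-fold, the phosphatase Dusp2 9.93-fold, the costimulatory ligand Icosl 9.80-fold, the AP-1 repressor Jdp2 9.68-fold, Exoc3l4 9.49-fold, Olr1 8.68-fold and Stat5a 8.20-fold. The scavenger receptor Marco was 28.0-fold higher, the formyl peptide receptor Fpr2 12.4-fold, the collagen crosslinking enzyme Lox 10.3-fold, Lcn2 9.19-fold and the guanylate binding protein Gbp6 6.10-fold. With the mean of a gene's probe sets Snn was at -2.02, Icosl at -1.75, Jdp2 at -1.79 and Lox at 2.54. Of the 232 Pam3CSK4-induced genes, 129 (55.6%, exact 95% binomial interval over genes 49.0% to 62.1%) were more than 2-fold lower and 17 more than 2-fold higher, and the median difference was -1.11. At a threshold of 3-fold 35.8% were lower. At least 3-fold over unstimulated were 94 (40.5%), against 72.5% of the MDP-induced genes, and 25 were at or below the unstimulated level, Cd83 (-1.25) and Egr2 (-1.94 or lower) among them.

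Of the cytokine genes 9 of 21 were 2-fold lower after Pam3CSK4 pretreatment and none 2-fold higher, with a median of -0.78. Il1b (-2.06), Tnfsf9 (-1.96) and Il1a (-1.95) were 2-fold lower, Il10 was at -1.85 and Tnf at -1.61, while Il6 was at -0.72. Il1b and Il6 were still 43.4-fold and at least 12.3-fold over unstimulated. Of the NF-kB feedback genes 11 of 27 were 2-fold lower, including Socs3 (-2.24), Nfkbie (-2.26) and Tnfaip3 (-1.01), and 4 were 2-fold higher, including Irak3, a kinase-like inhibitor of Toll-like receptor signalling, at 1.78. Chemokine genes went both ways. There were 3 of 21 past 2-fold on the lower side, including Cxcl1 (-2.01) and Ccl22 (-1.57), and 4 on the higher side, including Cxcl5 (at least 1.94), Ccl8 (1.65) and Ccl5 (1.05), and the median was 0.00, at percentile 46.3. Of the antimicrobial and tissue effector genes 6 of 22 were 2-fold higher, led by the complement gene Cfb (4.27), haptoglobin, Hp (3.96), and the protease inhibitor Slpi (3.40), and 3 were 2-fold lower, Ptgs2 (-2.19) the furthest. Interferon-stimulated genes stood out as a group, with 20 of 27 2-fold higher and a median of 1.33 at percentile 100. Isg20 (3.26), Iigp1 (3.14), Oasl1 (3.13) and Irf7 (2.49) were among the highest. Over all genes 438 were at least 2-fold higher and 418 at least 2-fold lower (154 and 165 at 3-fold). On this array the 18S ribosomal RNA control probe sets had a median 1.70 above the unstimulated array, against at most 0.48 on the other stimulated arrays.

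In cells pretreated with Pam3CSK4, MDP left most MDP-induced genes at or above their level in naive cells given MDP. Saa3 was 37.7-fold higher, Ccl5 13.9-fold, Mmp14 8.88-fold, Il1a 8.17-fold and Il1b 6.57-fold. There were 5 of the 40 genes (12.5%, interval 4.19% to 26.8%) more than 2-fold lower, namely Cd83 (-2.99), Olr1 (-1.77), Nfkbie (-1.41), Icosl (-1.30) and the lysolipid receptor Gpr132 (-1.28). Icosl (-0.72) and Gpr132 (-0.87) were short of 2-fold with the mean of their probe sets, with 32 added to the linear values 6.45% of the induced genes were lower, and at a threshold of 3-fold 2 of the 40. Another 15 were more than 2-fold higher, the median difference was 0.54, and 31 (77.5%) were at least 3-fold over unstimulated, against 41.8% of the Pam3CSK4-induced genes. Socs3 was 3.85-fold higher and Acod1 2.24-fold higher than in naive cells given MDP. Outside the MDP-induced set, Marco was 83.2-fold higher, Lcn2 56.5-fold, arginase, Arg1, 40.5-fold from a naive value of 5.79 close to the array median (4.70 with 32 added), and Ptgs2 at least 12.5-fold, and Il6 was higher by at least 4.63 on the log2 scale. Over all genes 390 were at least 2-fold higher and 311 at least 2-fold lower (170 and 86 at 3-fold). No array with Pam3CSK4 pretreatment lacked a second ligand, so these levels include whatever the first 24 h had left.

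Among interferon-stimulated genes 24 of 27 were 2-fold higher in cells given MDP after Pam3CSK4 than in naive cells given MDP, with a median of 1.63, and Isg20 (3.54), Oasl1 (3.09) and Iigp1 (2.90) were highest. Of the antimicrobial genes 12 of 22 were 2-fold higher (median 1.19, or 3.25 over the genes above the 75th percentile of the higher array), as were 10 of 21 chemokine genes (median 0.85), with Cxcl5 higher by at least 2.08, and 6 of 21 cytokine genes (median 0.55). Immediate early genes had a median of -0.19, with Egr2 (-2.68 or lower), Maff (-1.71), Ier2 (-1.15) and Fos (-1.10) 2-fold lower and Btg2 (1.00) at the 2-fold line. Irak3 was 7.28-fold higher and Tlr2 was at -0.43. The fungal glucan receptor Clec7a was 2-fold lower (-2.19).

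With Pam3CSK4 after MDP pretreatment, 225 of the 232 Pam3CSK4-induced genes were within 2-fold of their level in naive cells given Pam3CSK4. No array with MDP pretreatment lacked a second ligand, so these levels include whatever the first 24 h had left. Il1b differed from naive cells given Pam3CSK4 by 0.02, Tnf by 0.03, Socs3 by 0.04, Il10 by 0.04 and Cxcl2 by 0.10, and Il6 was 1.94-fold higher. Of the 232 Pam3CSK4-induced genes 1 (0.431%, interval 0.0109% to 2.38%), the adhesion receptor gene Selp, was more than 2-fold lower (-1.55), though short of it with the mean of its probe sets (-0.96). Selp was also 2-fold lower after Pam3CSK4 (-2.68 or lower, or -1.44 with the mean of its probe sets). The genes more than 2-fold higher numbered 6, the highest being Gbp6 (2.07), Cxcl11 (1.51, or 0.85 with the mean of its probe sets), Fpr2 (1.43), Gem (1.33) and Ccrl2 (1.23). The median difference was 0.19, and 219 (94.4%) were at least 3-fold over unstimulated. Over all genes 54 were at least 2-fold higher and 4 at least 2-fold lower, 16 and 1 at 3-fold, and the lower genes numbered 1 with the mean of a gene's probe sets and 2 with 32 added. Interferon-stimulated genes were the group furthest from their naive level, with all 27 of 27 above it, 12 of them 2-fold higher and a median of 0.84. Iigp1 (1.88), Isg20 (1.84), Irf7 (1.73) and Oasl1 (1.69) were the highest. Costimulation and antigen presentation genes had a median of 0.47, cytokines of 0.27 and NF-kB feedback genes of 0.10, with no member of the NF-kB list past 2-fold. Ighm was again lower in pretreated cells, by a log2 difference of -1.89, or -0.39 with the mean of its probe sets.

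**Figure D2:**
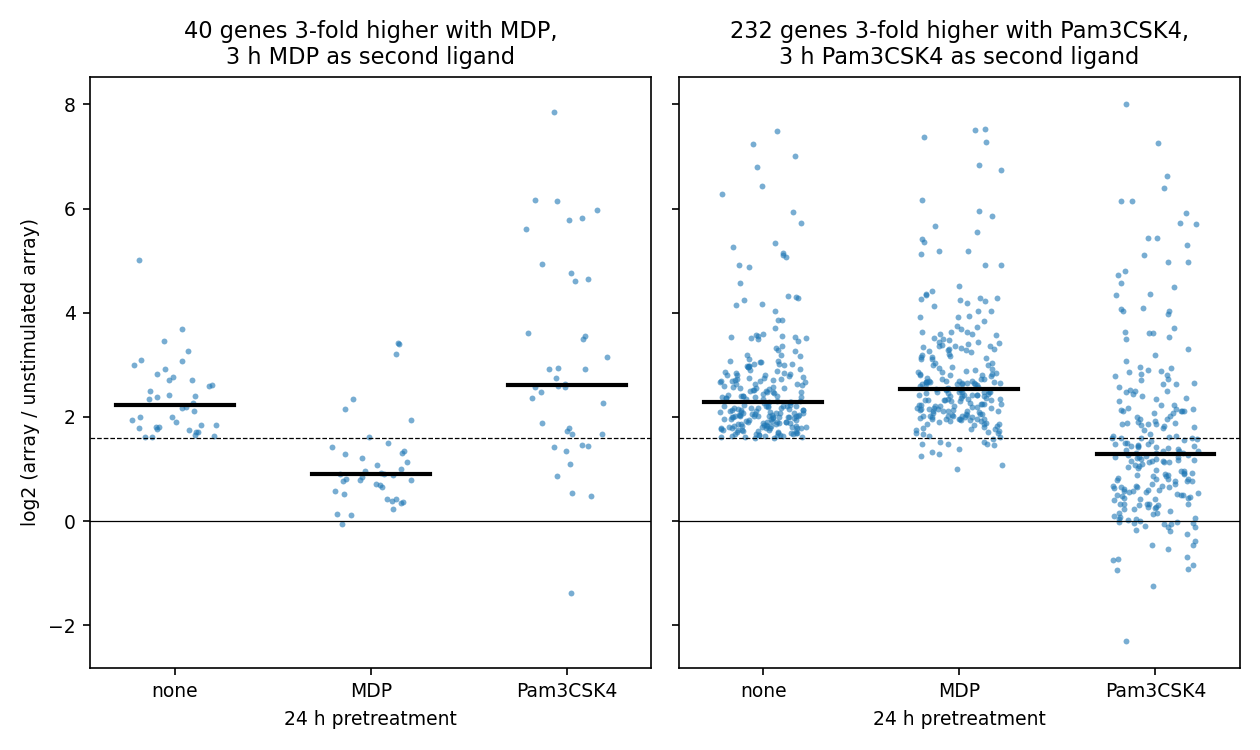
Log2 ratio over the unstimulated array of the 40 MDP-induced genes with MDP as second ligand (left) and of the 232 Pam3CSK4-induced genes with Pam3CSK4 as second ligand (right), by pretreatment, 1 array each. Points are genes, black bars are medians (2.23, 0.90 and 2.62 on the left, 2.28, 2.54 and 1.28 on the right), and the dashed line marks 3-fold.

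Induced genes were mostly lower after the same ligand than after the other. Of the 40 MDP-induced genes 38 were higher with MDP after Pam3CSK4 than with MDP after MDP, and 9 were 2-fold lower after MDP and 2-fold higher after Pam3CSK4 against naive cells. However, 39 of the 40 were also induced by Pam3CSK4, and no pretreated array lacked a second ligand. Their higher level after Pam3CSK4 cannot be told apart from what the first 24 h had left. Of the 232 Pam3CSK4-induced genes 201 were lower with Pam3CSK4 after Pam3CSK4 than with Pam3CSK4 after MDP, 143 of them by at least 2-fold. Given Pam3CSK4, Tnf had a level of 12.89 in naive cells, 12.92 after MDP and 11.28 after Pam3CSK4.

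The arrays with MDP and with Pam3CSK4 as second ligand differed in many genes after MDP pretreatment, and hardly differed after Pam3CSK4 pretreatment. After MDP, Pam3CSK4 gave at least 39.7-fold more Il6 than MDP did, 84.1-fold more Il1a (-5.79 for MDP against Pam3CSK4 with 32 added to the linear values), 76.7-fold more Socs3, at least 54.1-fold more Ptgs2 (-5.06 on the same scale with 32 added) and at least 15.7-fold more Shisa3. Cnr2 (3.26, or 2.66 with 32 added), Dusp6 (3.20), Cxcr4 (3.18), Mex3b (at least 2.62) and Thbd (3.13) were among the highest with MDP relative to Pam3CSK4. In these cells 439 genes were at least 2-fold higher with Pam3CSK4 and 259 with MDP (237 and 70 at 3-fold). This contrast and the one in naive cells share no array. Their 2-fold sets had 238 genes in common for Pam3CSK4, where independent lists would share 6.15, and 111 for MDP, or 69 with the mean of a gene's probe sets, where independent lists would share 1.84. No gene was past 2-fold in opposite directions. After Pam3CSK4, only Il6 differed by 2-fold between the second ligands, 2.09-fold higher with MDP. Il1b differed by 0.34, Ptgs2 by 0.60, Acod1 by 0.02 and Marco by -0.03. The correlation over probe sets between these 2 arrays was 0.998, and the spread of the gene differences, as a robust SD, was 0.111, the lowest of any pair of the 7 arrays. Whether the 2 arrays carry the same RNA could not be decided. No array had Pam3CSK4 pretreatment without a second ligand. A lost response to the second ligand therefore cannot be told apart from a like response to both ligands.

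**Figure D3:**
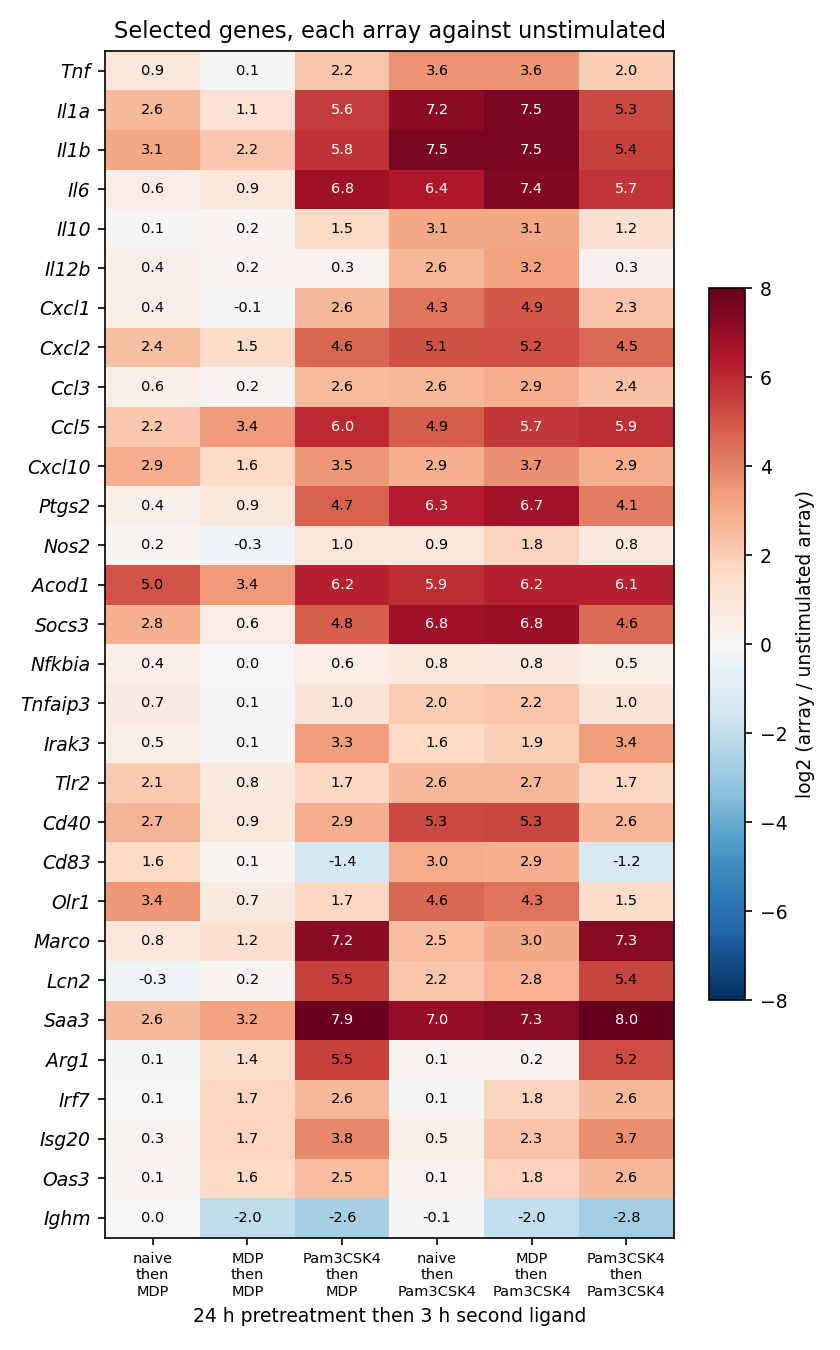
Log2 ratio over the unstimulated array of 30 genes down the side on the 6 stimulated arrays across (pretreatment then second ligand), with the ratio written in each cell. Ratios are from the deposited values, also where a value lies below its array's median. Il1b runs from 2.16 with MDP after MDP to 7.52 with Pam3CSK4 after MDP, and Marco from 0.85 with MDP in naive cells to 7.25 with Pam3CSK4 after Pam3CSK4.

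Some genes differed between naive and pretreated cells whichever ligand came second. The comparisons with MDP and with Pam3CSK4 as second ligand share no array, so each gene past 2-fold in both was seen on 4 separate arrays. This is no replicate check, since a culture or array batch that goes with pretreatment would also give more agreement than independent lists. The arrays with Pam3CSK4 pretreatment had a correlation of 0.998. Both naive stimulated arrays had a higher B1 repeat control value (13.4 and 13.3, against at most 13.1 on the others). After MDP pretreatment 19 genes were 2-fold higher with either second ligand, where independent lists would share 0.208. Irf7, Isg20, Oas3, Zbp1 and Gbp6 were among them, together with Slfn1, Plac8 and Ifi213, which were chosen after their values were seen and are named here for their size. Slfn1 differed by 2.15 with MDP and by 2.59 with Pam3CSK4, or by 1.07 and 1.25 with the mean of its probe sets. Ighm was the gene 2-fold lower in both, and with the mean of a gene's probe sets there was none. After Pam3CSK4 pretreatment 237 genes were 2-fold higher with either second ligand and 183 were 2-fold lower, where independent lists would share 9.39 and 7.15, and 18 went in opposite directions. Marco (6.38 with MDP and 4.80 with Pam3CSK4), Arg1 (5.34 and 5.08, or 4.70 and 4.46 with 32 added), Cfb (5.33, or 4.62 with 32 added, and 4.27) and Hp (4.80 and 3.96) were among the higher genes. Cd83, Egr2, Clec10a (-2.68 and -2.86) and Ccnb2 (-2.43 and -2.22) were among the lower.

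Of 15 genes of macrophage identity, 2 were 2-fold higher and 2 lower with MDP after Pam3CSK4 against naive cells, 3 were higher and 0 lower with Pam3CSK4 after Pam3CSK4, and none was past 2-fold after MDP pretreatment with either ligand. Itgam was 2.46-fold higher with MDP after Pam3CSK4 than with MDP alone. Trem2 differed by -1.05, or by 0.05 without less specific probe sets, so its direction is open. Housekeeping genes had medians between -0.08 and 0.00 in the 6 comparisons of naive cells with unstimulated cells and of pretreated with naive cells, with no member past the threshold. T and NK cell markers had medians of 0.17 with MDP and 0.20 with Pam3CSK4 over unstimulated, dendritic cell markers 0.18 and 0.18, and mast cell and erythroid markers 0.07 and 0.00, with no member past 3-fold. With the mean of its probe sets, the dendritic cell marker Fscn1 was past 3-fold with Pam3CSK4 (1.91). Several of these markers, among them Ccr7, Xcr1, Cpa3, Kit, Thy1 and Gzma, were below the array medians on both arrays of these comparisons. Their values cannot be told from background. In cells pretreated with Pam3CSK4, 1 of 10 neutrophil markers was 2-fold higher with MDP than in naive cells, and 1 was higher and 1 lower with Pam3CSK4, with medians of 0.39 and 0.41. S100a8 was at 1.17 and 1.05, Mpo was below the array medians, and Ltf, a granule protein gene, was at -0.70 and -1.16 (-0.93 with 32 added). Among stromal markers, Dcn (3.50-fold and 2.79-fold, or log2 differences of 1.06 and 0.75 with the mean of its probe sets) and Thbs1 (4.19-fold and 7.20-fold) were higher in the same cells, and Col1a1 was below the array medians.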

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

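The tests of gene selection in the next paragraph were written before their own values were computed, but after the lower levels themselves and a related value had been seen, namely that 19.8% of the genes induced by Pam3CSK4 were 2-fold lower with MDP after MDP. The tests of the second ligand and of the interferon-stimulated genes were chosen only after the results were seen.

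Induced genes such as Socs3, Acod1 and Cd83 were lower after a first exposure to the same ligand, and part of this could come from picking genes on the array that they are then compared with, since a gene picked for a high value tends to be lower elsewhere. In place of the MDP-induced genes, the 40 genes with the largest increase over unstimulated on the naive Pam3CSK4 array were taken. That array takes no part in the MDP comparison. With MDP after MDP against MDP alone, these 40 genes had a median of -0.92, and 47.5% were 2-fold lower. Of random lists, 95% lay between -0.03 and 0.09. The 325 genes 3-fold over unstimulated on the array with MDP before Pam3CSK4 had a median of -0.64 with Pam3CSK4 after Pam3CSK4, where random lists lay between 0.00 and 0.07, and 130 were 2-fold lower. These argue against selection as the whole cause, but the medians were -1.32 and -1.11 in the induced genes themselves, so part of the size may be selection. Variation between cultures stays open, with 1 array per group.

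After Pam3CSK4 pretreatment the arrays with MDP and with Pam3CSK4 as second ligand were close, and 1 explanation is that they carry the same RNA. The MDP-induced genes had a median difference between them of 0.20, outside the -0.04 to 0.02 of 95% of random lists, and 6 of 40 were below 0. Random lists treat genes as independent, so an array difference that moves these genes together could also give this value. The 18S control probe sets were higher with Pam3CSK4 as second ligand (1.70 over unstimulated, against at most 0.48 on the other stimulated arrays). The value therefore cannot decide whether the RNA was the same. Cells that no longer respond to a second ligand cannot be told apart from cells that respond alike to both, since 0 arrays had Pam3CSK4 and no second ligand.

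Interferon-stimulated genes such as Irf7, Oas3 and Isg20 were higher after MDP pretreatment with either second ligand. Low values on the 2 naive stimulated arrays alone stay open. The lower of the medians over unstimulated on the arrays with MDP pretreatment was 1.20, but naive cells given a ligand were already at 0.95 and 0.83, so this value cannot decide it. For a shift of whole arrays, the smallest gap between the interferon-stimulated and housekeeping medians over both array pairs and 3 scalings was 0.29. This was just under the bound of 0.3 set for the test, which did not decide it. The median over all genes was -0.01 with MDP after MDP and 0.00 with Pam3CSK4 after MDP, against 0.34 and 0.84 for the interferon-stimulated list. Matched random lists were at 0.00 and 0.02. These values argue only against a shift of whole arrays left in the deposited values as the cause of the higher list medians. Normalization brings array medians close together, so the median over all genes cannot show a shift that was present before it. A culture or array batch that goes with pretreatment also stays open, since Ighm, a B cell gene, was lower on all 4 pretreated arrays than on all 3 others, with a gap of 1.89, although the mean of its probe sets differed only by -0.51 with MDP after MDP, and no array tests a response to MDP that outlasts the first 24 h.

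Several values had opposite signs after the pretreatments, and in each of these cases the difference was not tested. The median of the MDP-induced genes with MDP was -1.32 after MDP and 0.54 after Pam3CSK4, a difference of 1.85. The median of the Pam3CSK4-induced genes with Pam3CSK4 was -1.11 after Pam3CSK4 and 0.19 after MDP, a difference of 1.30. The cytokine median with Pam3CSK4 was -0.78 after Pam3CSK4 and 0.27 after MDP, a difference of 1.05. The chemokine median with MDP was -0.35 after MDP and 0.85 after Pam3CSK4, a difference of 1.20. Acod1 with MDP was at -1.61 after MDP and 1.17 after Pam3CSK4, a difference of 2.78, and Socs3 at -2.24 and 1.95, a difference of 4.18.

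In values outside the gene comparisons, the 18S ribosomal RNA control probe sets on the array with Pam3CSK4 before Pam3CSK4 had a median 1.70 above unstimulated, and the highest of the other 5 stimulated arrays was at 0.48. Among probe sets without a single gene name, 39 were 3-fold higher with Pam3CSK4 than unstimulated in naive cells, and 1 with MDP.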

How the results depend on the processing

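Tests with probe sets counted singly were chosen after seeing the data, and the others were fixed before. Of 352 recomputed counts and percentages 277 stayed within 1.5 times or inside their interval and 75 moved. Of 20729 recomputed gene differences and list medians 20543 stayed, 185 moved and 1 reversed among called values, namely Trem2 with MDP after Pam3CSK4, at 0.048 without less specific probe sets. Centring on medians, centring on housekeeping genes, cyclic loess, the median filter and leaving out less specific probe sets each moved 0 of 34 counts and percentages, and the largest shift of a comparison's median was 0.06, 0.10 and 0.08 under the first 3. No paired analysis was possible because all labels carry 1 shared number and each group has 1 array. Signal near background limits the folds of low genes, and adding 32 to the linear values shrinks them. For the values below, the cause was not tested.

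With the mean of a gene's probe sets, 73 genes were 3-fold lower with Pam3CSK4, 80 were higher with MDP than with Pam3CSK4 in naive cells, 44 were higher and 34 lower with MDP after MDP than with MDP alone, 0% of Pam3CSK4-induced genes were 2-fold lower after MDP, and 1 gene was 2-fold lower with Pam3CSK4 after MDP. Shared by naive and MDP-pretreated cells were 69 genes higher with MDP than with Pam3CSK4, and 0 genes were lower with either second ligand after MDP. With the 75th percentile filter 0 genes were 3-fold lower with MDP, 40 were higher and 47 lower with MDP after MDP, and 2 were lower with Pam3CSK4 after MDP. With 32 added these were 0, 37, 42 and 2, and 6.45% of MDP-induced genes were lower with MDP after Pam3CSK4.

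With 2-fold for induction, 106 genes were induced and 31 lowered by MDP, 413 induced and 354 lowered by Pam3CSK4, and 96 induced by both. Of them 42.5% were lower with MDP after MDP and 43.3% with Pam3CSK4 after Pam3CSK4.

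With 3-fold in place of 2-fold, 28 genes were higher with MDP and 105 with Pam3CSK4 in naive cells, 70 and 237 after MDP, and 0 with MDP after Pam3CSK4. Against naive cells 8 were higher and 11 lower with MDP after MDP, 170 and 86 with MDP after Pam3CSK4, 154 and 165 with Pam3CSK4 after Pam3CSK4, and 16 and 1 with Pam3CSK4 after MDP. Of induced genes 25% were lower with MDP after MDP, 35.8% with Pam3CSK4 after Pam3CSK4 and 0% with Pam3CSK4 after MDP, and 5% with MDP after Pam3CSK4. Naive and MDP-pretreated cells shared 26 genes higher with MDP and 93 with Pam3CSK4, 7 were higher with either second ligand after MDP, 87 higher and 58 lower after Pam3CSK4, and 5 lay apart by pretreatment.

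With 2-fold for still induced, 37.5% were over unstimulated with MDP after MDP, 90.0% with MDP after Pam3CSK4, 59.5% with Pam3CSK4 after Pam3CSK4 and 100% with Pam3CSK4 after MDP. With genes chosen by the other ligand these were 3.45%, 41.8%, 72.5% and 100% at 3-fold, 19.8% were lower with MDP after MDP, and 0% with Pam3CSK4 after MDP.

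With probe sets counted singly, 3 were lowered by MDP, 417 induced and 179 lowered by Pam3CSK4, 216 higher with MDP and 527 with Pam3CSK4 in naive cells, and 458 and 828 after MDP. Against naive cells 118 were higher and 86 lower with MDP after MDP, 672 and 567 with MDP after Pam3CSK4, 704 and 804 with Pam3CSK4 after Pam3CSK4, and 95 and 8 with Pam3CSK4 after MDP. Naive and MDP-pretreated cells shared 189 higher with MDP and 453 with Pam3CSK4, 34 were higher and 2 lower with either second ligand after MDP, 385 and 316 after Pam3CSK4, and 19 lay apart by pretreatment.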

Other observations

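Cell cycle genes stood above their naive level after MDP pretreatment. With MDP as second ligand all 21 of 21 were above it, with a median of 0.63 at percentile 100, and Rrm2 (1.03) and Mcm5 (1.01) were at the 2-fold line, short of it with 32 added to the linear values (0.99 and 0.98). With Pam3CSK4 as second ligand 18 of 21 were above it, with a median of 0.53, and none was 2-fold higher. Pam3CSK4 alone gave a median of -0.44 against unstimulated, with the cyclin Ccnd1 3-fold lower (-1.95). After Pam3CSK4 pretreatment 6 of 21 were 2-fold lower and none 2-fold higher with MDP, and 4 were lower and 1 higher with Pam3CSK4. Lower with both were Ccnb2 (-2.43 and -2.22), Cdc20 (-1.66 and -1.67), Plk1 (-1.27 and -1.10) and Birc5 (-1.24 and -1.22), while Rrm2 was at 0.71 and 1.67 and Mcm5 at 0.43 and 0.91.

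Of 12 alternative activation markers 4 were 2-fold lower and 1 higher with MDP after Pam3CSK4 pretreatment, and 3 lower and 1 higher with Pam3CSK4, with medians of -0.36 with MDP and -0.42 with Pam3CSK4. The lectins Clec10a (-2.68 and -2.86) and Mrc1 (-1.61 and -1.36) were 2-fold lower with both, and Arg1 was higher by 5.34 and 5.08, or 4.70 and 4.46 with 32 added. Arg1 was also 2.41-fold higher with MDP after MDP, though short of 2-fold with 32 added (0.92), and differed by 0.01 with Pam3CSK4 after MDP. Of the oxidative stress genes, Hmox1 (1.05 and 1.42) and the glutathione synthesis gene Gclm (1.32 and 1.82) were 2-fold higher after Pam3CSK4 pretreatment, and the metallothionein Mt2 (-1.03 and -2.23) was lower, with MDP only near the 2-fold line. With MDP after MDP this list had a median of -0.24. Glycolysis and hypoxia genes had medians of 0.34 and 0.38 after Pam3CSK4, with Bnip3 (1.15), Egln3 (1.08, or 0.84 with the mean of its probe sets) and Ero1a (1.04) higher when MDP came second. Sterol synthesis genes had medians of -0.13 and -0.26, with Sqle (-1.04) and Idi1 (-1.01) near the 2-fold line on the lower side with MDP as second ligand, and the sterol reductase Dhcr7 (1.51) 2-fold higher with Pam3CSK4. Of the 16 genes, Ch25h, which makes 25-hydroxycholesterol, was 2-fold lower with the same ligand as before, at -1.18 for MDP and -1.45 for Pam3CSK4, and higher with Pam3CSK4 after MDP (1.22).

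There were 12 genes that lay at least 2-fold apart between every array with pretreatment and every array without it, chosen after their values were seen. Ighm was lower, with a gap of 1.89 between the nearest arrays. At 3-fold they numbered 5, and 9 with the mean of a gene's probe sets. Higher were Ifi213 (1.80), Ms4a4c (1.76), Slfn1 (1.76), Irf7 (1.65), Slfn4 (1.49), Oas3 (1.47), H2-T24 (1.28), Plac8 (1.28), Isg20 (1.24), Ddx60 (1.20) and Ifi209 (1.11).

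On 2 naive stimulated arrays the control probe set for the B1 repeat was at 13.4 (MDP) and 13.3 (Pam3CSK4), and between 12.9 and 13.1 on the others. Where a gene had several probe sets above the array median, they went the same way in 13 of 15 MDP-induced genes and in 111 of 112 Pam3CSK4-induced genes, and all were past 3-fold in 5 and 63.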
